A study of Mus musculus with 3 samples.

How the data were processed

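RNA from SiO2-treated mouse spleens, from spleens that received SiO2 and 3TF-3C, and from normal mouse liver was hybridised to Agilent mouse arrays with 1 dye, Cy3. Per the labels' protocols, RNA was purified with a blood RNA kit that lyses red and white cells separately and digests DNA on the column, globin messages were then depleted, and Cy3-labelled cRNA was made by linear amplification. That protocol is written for blood, and how it was adapted to spleen and liver is not given in the sources used here. Each deposited scanner file holds the linear fluorescence intensity of the spots of 1 array after background subtraction and detrending, not yet scaled between arrays. Per the file headers, intensities were extracted with Feature Extraction 11.0.1.1, whereas the submitters' processing notes name Agilent Feature Extraction 9.1. The headers give array design 026655 and genome build mm9. The 3 arrays lay on the same slide and were scanned together, so slide and scan do not separate the groups, although each group has its own position on the slide. The values of the authors' deposited series table are log2, since each of its columns correlated best with the log2 intensity of its own array (r from 0.993 to 0.996). Its column medians were 5.91, 5.91 and 5.91, its columns are not centred on 0, and all 3 have the same maximum of 16.58. The equal maxima and near-equal medians point to matching of whole distributions between arrays, as quantile normalization does. The method is not given in the sources used here. The deposited series table lists 26049 probes, and the filter behind that number is not given in the sources used here either.

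Processed signals were taken on the log2 scale. Control spots and spots flagged as non-uniform or as population outliers were left out (182, 283 and 469 of 43020 for the SiO2 spleen, the SiO2-3TF-3C spleen and liver), and spots of the same probe were averaged. Each array was then scaled by subtracting its 75th percentile. The 75th percentile corresponded to an intensity of 569, 515 and 390, and the median negative control spot to 1.94, 1.56 and 1.85, in the same order. No spot was marked as saturated (0 on each array). The files carry no gene names, so probes were named through the unversioned RefSeq accession of the probe and a table of RefSeq genes on the GRCm38.p6 assembly, used for names alone because its build is not that of the arrays; for that reason no coordinates are given. Of 39112 probes 27038 (69.1%) received a symbol, and the other 12074 were not used here by name. The 20546 genes were each represented by the brightest probe over the 3 arrays. Probes of the same gene differed by over 1 log2 in 4.81% of the 4279 genes with several measured probes between the 2 spleen samples, in 19.6% between liver and SiO2 spleen and in 15.3% between SiO2-3TF-3C spleen and liver.

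A gene was called measured on an array where its probe was well above background by the scanner software's own test. A gene measured on only 1 side of a comparison has a bound, written as at least so many fold, which sets the dim side to the higher of its own signal and the lowest signal well above background on that array (-6.04, -6.19 and -5.57 on the scaled log2 axis). Bounds numbered 858, 1211 and 791 in the 3 comparisons, and 26, 30 and 14 of them had another probe that was well above background. Genes dim on both sides have no fold. Because each group has 1 array, genes were described by a rule of size (2-fold), with no test. Technical errors combine the 2 signal errors of the scanner software. Gene lists were set against 10000 random lists of equal size drawn from 20 bins of mean expression. A correlation across genes used genes well above background on at least 1 array. Unchanged arrays that share the control were simulated 100 times from the signal errors.

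The groups, the 3 comparisons, 42 gene lists with 3 unions, the alternatives and the rule for naming genes were fixed before the data were examined. The rule takes, per comparison, the 12 highest and 12 lowest differences among genes measured on both arrays and the 6 highest bounds in each direction, with at most 2 genes per family of symbols that share their first 3 letters, then up to 4 members per list with the largest differences in the SiO2-3TF-3C spleen, and a fixed set of anchor genes such as Alb, Hnf4a, Cd3e and Col1a1. The anchor Hbb-b1 had no probe matched here. Names that look like accessions or clone numbers, pseudogenes and mitochondrial genes were passed over. The pseudogene Serpina4-ps1 and the list members Hba-a1, Hbb-bt, Tlx1 and Nkx2-3 were named outside this rule after their values were seen, as were the Y-linked genes and the genes said to be so chosen in the last part.

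The alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the median or to housekeeping genes, the authors' deposited values, the mean over all probes of a gene, only genes well above background on all 3 arrays, no filter on dim genes, removal of saturated probes, and a 4-fold rule of size. The normexp setting was planned on mean spot signals and was run on the median spot signal and median local background, the columns at hand. Choosing each gene's probe without the liver array, and leaving out genes higher in liver, were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and limma 3.58.1 in R 4.3.3 for normexp. The steps were tested on simulated data for the comparison of the 2 spleen samples. With 200 genes changed, the 2-fold rule found 99 of 100 genes changed by 1.5 log2 and all 100 changed by 3, and called 31 of 16902 unchanged genes (0.183%). The changed genes were well above background on all 3 arrays and of middle level on the SiO2 spleen array. Detection was held the same on every array, and the only noise was the scanner software's signal error. These shares therefore do not cover bounds or differences between pools. The remaining comparisons in the series design, of PBS-treated spleens and of cultured cells, were not analysed here.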

Results

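Gene expression was measured in 3 RNA samples from female mice, each on 1 single-colour Agilent array. The first sample came from spleens treated with SiO2 (silica), here the SiO2 spleen. The second came from spleens given SiO2 and a further treatment that the labels call 3TF-3C without spelling it out, here the SiO2-3TF-3C spleen. The third was normal liver, which the labels call a positive control. Spleens were collected on day 82, and the series design states that 5 samples were pooled per group, without saying whether this includes the liver. Each group therefore has 1 array and no replicate. No p-value, standard error or test between groups can be given, and the number of arrays limits the precision of every value below. Values after ± are the scanner software's technical error of a log2 difference and leave out the spread between animals. Of 43020 spots, 79.9% were well above background on the SiO2 spleen array, 81.3% on the SiO2-3TF-3C spleen array and 77.2% on the liver array. The median standard deviation of replicate spots of 1 probe was 0.0640, 0.0662 and 0.0832 on the log2 scale, in the same order. The X-inactivation transcript Xist was well above background on all 3 arrays, and the 4 Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were on none, which is the pattern of the female sex the labels give. Xist differed by -0.43 between the spleen samples.

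The first comparison asks how expression in the SiO2-3TF-3C spleen differed from that in the SiO2 spleen. Genes of the hepatocyte, the main cell type of the liver, were far higher in the SiO2-3TF-3C spleen. Of 212 hepatocyte genes measured, 175 were at least 2-fold higher, 0 were at least 2-fold lower and 37 differed by less than 2-fold. The median log2 difference was 4.49, at percentile 100 of 10000 random lists matched on expression. It was 2.80 with normexp background correction and 3.17 among genes well above background on all 3 arrays. Albumin (Alb) was 1021-fold higher, the plasma protein Ahsg differed by 10.04 ± 0.22 on the log2 scale, and Ttr, the carrier of thyroxine and retinol-binding protein, was at least 1187-fold higher. Single marker genes of other liver cells were higher as well, in lists of which most members were not (2 of 9 Kupffer cell and 1 of 13 stellate cell genes passed 2-fold). The Kupffer cell genes Clec4f and Vsig4 differed by 6.41 ± 0.34 and 4.11 ± 0.23, and Colec11, a gene of hepatic stellate cells, by 2.79 ± 0.22.

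The hepatocyte lists covered secretion, detoxification and metabolism. All 25 measured plasma protein genes were at least 2-fold higher in the SiO2-3TF-3C spleen than in the SiO2 spleen, with a median log2 difference of 6.77. Of 19 coagulation and fibrinolysis factors, 16 were at least 2-fold higher and 3 were not, with a median of 6.32. The fibrinogen chain Fgb differed by 9.57 and the kininogen gene Kng1 by 9.84, while the fibrinogen chain Fgg was at least 1652-fold higher. Of 18 liver complement genes 13 were at least 2-fold higher (median 4.50), among them Cfi at 8.85 and C8b at 6.82. Of 19 acute phase genes 17 were higher (median 2.95), with Saa2 at 7.07 and Fgl1 at 6.94. Among 29 cytochrome P450 genes 26 were at least 2-fold higher and 3 were not (median 5.54). Cyp2f2 differed by 9.03, Cyp2e1 by 6.90 ± 0.24, and Cyp3a11 was at least 468-fold higher. Of 32 phase 2 enzymes and hepatic transporters 27 were higher (median 4.10), led by the carboxylesterases Ces3a at 9.64 and Ces1c at 8.26. Bile acid synthesis genes were higher for 13 of 14 (median 3.78), among them Cyp7a1, the rate-limiting enzyme of the pathway, at 3.08 ± 0.27.

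The metabolic lists went the same way. All 8 urea cycle genes were at least 2-fold higher, with a median log2 difference of 2.17. Arg1 differed by 7.44 ± 0.30, Cps1 by 4.77 ± 0.22 and Ass1 by 2.19, and Otc was at least 121.8-fold higher. Of 18 genes of glucose and glycogen metabolism 11 were higher and 7 differed by less than 2-fold (median 2.49). Pck1, a key enzyme of gluconeogenesis, differed by 8.16 and G6pc, which releases glucose, by 2.01. Of 23 amino acid catabolism genes 20 were higher (median 4.92), with Bhmt at 9.26, Tat at 2.76 and Fah at 2.94. Fatty acid and lipoprotein genes were higher for 17 of 27 (median 1.46), with Acsm1 at 6.83 and the fatty acid binding protein Fabp1 at 6.57. Each of these lists lay at percentile 100 of the matched random lists. The lowest medians under the other processings were 3.82 for coagulation, 2.59 for complement, 3.63 for cytochrome P450, 1.90 for phase 2 and transporter, 1.94 for bile acid, 1.46 for glucose and 0.96 for fatty acid genes.

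Of 22 hepatic transcription factors measured, 11 were at least 2-fold higher in the SiO2-3TF-3C spleen and 11 differed by less than 2-fold, with a median log2 difference of 1.17 that ranged from 0.23 to 1.78 under the other processings. Hnf4a, a central regulator of hepatocyte genes, differed by 8.37 ± 0.35, and the bile acid receptor Nr1h4 by 4.48. Foxa3 was at least 11.4-fold higher, because it was not well above background in the SiO2 spleen. Gata4 went the other way, at -0.55. Genes of the hepatocytes around the central vein were higher for 8 of 14 (median 1.87) and genes of those around the portal vein for 12 of 14 (median 5.08). Female-predominant liver genes were higher for 14 of 17 (median 3.71) and male-predominant liver genes for 12 of 18 (median 2.24), with Mup20 at 9.57 and Mup3 at 9.40. In the hepatoblast and biliary list 7 of 18 genes were at least 2-fold higher (median 0.48). The keratin gene Krt18 differed by 4.60, the bile duct keratin Krt19 was at least 1.63-fold higher, and the fetal liver gene Afp was at -0.51. The lowest medians under the other processings were 0.82 for the central vein, 2.28 for the female-predominant, 1.37 for the male-predominant and 0.23 for the hepatoblast and biliary list.

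**Figure D1:**
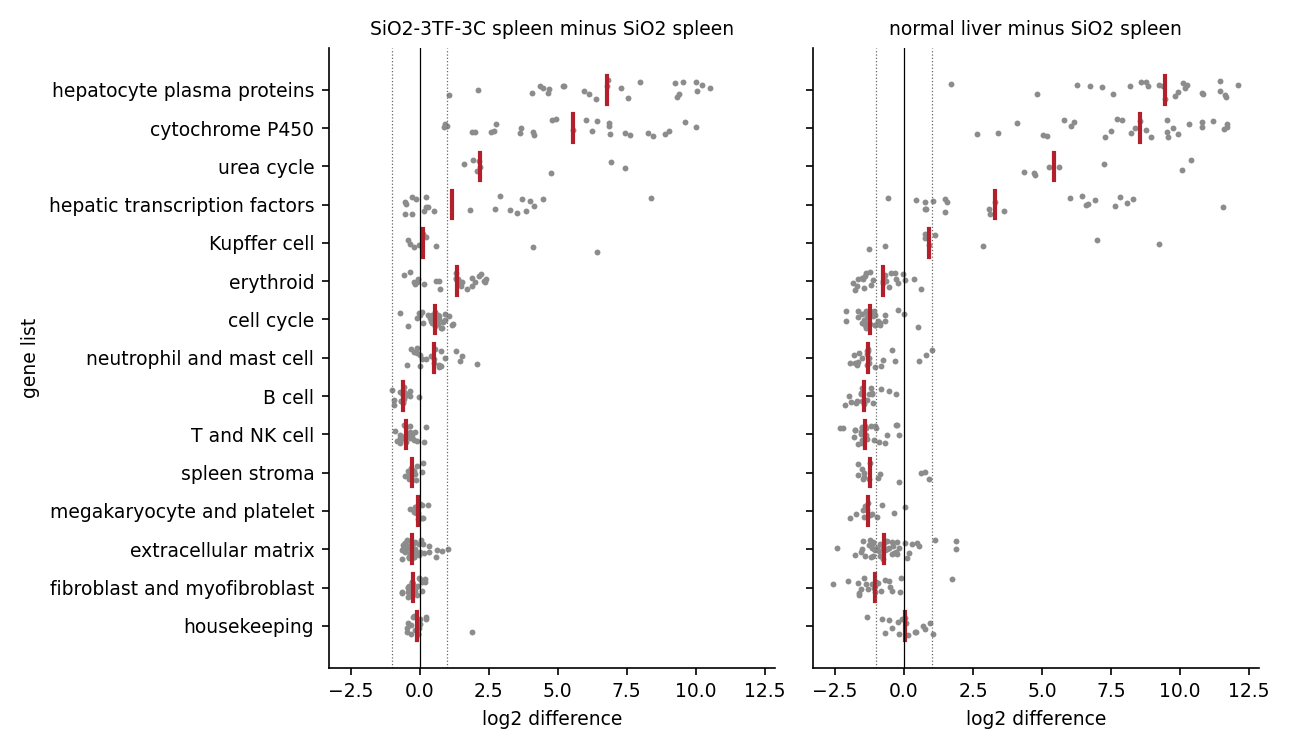
Log2 difference from the SiO2 spleen array (x axis) of each gene in 15 lists (y axis), in the SiO2-3TF-3C spleen (left) and in normal liver (right), with 1 array per group. Grey points are genes, red bars list medians and dotted lines 2-fold differences. Hepatocyte lists lie to the right on both sides (plasma protein medians 6.77 and 9.46), erythroid genes to the right only in the SiO2-3TF-3C spleen (median 1.36 against -0.75 in liver).

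Many genes of red cell formation were also higher in the SiO2-3TF-3C spleen than in the SiO2 spleen, and cell cycle and granulocyte genes by smaller amounts. Of 26 erythroid genes 16 were at least 2-fold higher, 0 were at least 2-fold lower and 10 were in between, with a median log2 difference of 1.36 at percentile 100 of the random lists. The red cell membrane genes Epb42 and Kel differed by 2.40 ± 0.21 and 2.35 ± 0.20, and Klf1, a regulator of globin genes, by 2.32 ± 0.20. The globin genes were not among them, with Hba-a1 at 0.15 and Hbb-bt at -0.22, and the RNA protocol in the labels, which is written for blood, includes a step that removes globin messages. The labels do not say how that protocol was adapted to spleen and liver. Alas2, the first enzyme of haem synthesis in red cells, differed by 0.60. Of 29 cell cycle genes 3 were at least 2-fold higher and 26 were not (median 0.56, percentile 100), with Mki67 at 1.21 ± 0.20, Ccna2 at 1.17 and Ube2c at 1.04. Of 22 neutrophil and mast cell genes 4 were at least 2-fold higher (median 0.51, percentile 100). These were the eosinophil granule genes Epx at 2.06 ± 0.21 and Prg2 at 1.51, and the neutrophil granule genes Ltf at 1.47 and Ctsg at 1.31. Megakaryocyte and platelet genes had 0 of 13 at least 2-fold apart and a median of -0.07, with Pf4 at -0.16 and Gp9 at -0.20.

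Lymphocyte genes were lower in the SiO2-3TF-3C spleen by less than 2-fold for nearly all members. Of 46 measured, 1 was at least 2-fold lower, 0 were higher and 45 differed by less than 2-fold, with a median log2 difference of -0.57 at percentile 0 of the random lists. The B cell list had a median of -0.60, with Cd72 at -1.01 ± 0.20, Cr2 at -0.94 and Cd79a at -0.57. The T and NK cell list had a median of -0.51, with Lat at -0.89 and Cd3e at -0.45. The median over all genes was -0.15. Extracellular matrix and fibroblast genes had a median of -0.27, with 1 of 70 genes at least 2-fold higher, 0 lower and 69 in between. Col1a1 was at -0.08, Col3a1 at -0.40 and the smooth muscle actin Acta2 at -0.19, and the member past 2-fold was the metalloproteinase inhibitor Timp1 at 1.02. Spleen stroma genes had 0 of 14 past 2-fold and a median of -0.30, with the spleen organ regulators Tlx1 at -0.14, Nkx2-5 at -0.42 and Nkx2-3 at -0.34.

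Among the other lists, mesothelial, skeletal muscle, interferon response and plasma cell genes stood furthest from the matched random lists, at percentiles 99.95, 0.03, 99.99 and 99.89. Macrophage and dendritic cell genes had a median of -0.23, with Vsig4 the only 1 of 27 past 2-fold. Kupffer cell genes had 2 of 9 past 2-fold (Clec4f and Vsig4, above) and a median of 0.11. Hepatic stellate cell genes had 1 of 13 (Colec11, above) and a median of 0.17, and endothelial genes 2 of 25 (median -0.05), Clec4g at 1.01 and Prox1 at least 3.54-fold higher. Plasma cell genes had 2 of 9 higher (median 0.47), Sdc1 at 1.65 and Derl3 at 1.05. Sdc1 was also far higher in liver, at 4.04 against the SiO2 spleen. Of 12 skeletal muscle genes 4 were at least 2-fold lower (median -0.62), among them Myl1 at -1.85 and Myh1 at -1.82, with Myh4 at least 4.13-fold lower. Pancreatic acinar, pancreatic islet and adipocyte genes had medians of 0.04, -0.17 and -0.13, each of which changed sign under at least 1 other processing. The members past 2-fold were Amy2a5 at 2.46, Car3 at 6.61, Slc2a4 at 2.14 and Adrb3 at 1.54. Amy2a5 and Car3 were also far higher in liver than in the SiO2 spleen, at 4.34 and 10.09, whereas Slc2a4 was at -1.27 there. Mesothelial genes had 3 of 7 higher (median 0.70), with Msln at 2.86 and Gpm6a at 1.02, and the other was the keratin Krt18, which was also far higher in liver (8.11 against the SiO2 spleen). Interferon response genes had 2 of 19 higher (median 0.32), Iigp1 at 1.21 and Rsad2 at 1.17. Inflammatory cytokine and chemokine genes had 1 of 24 (median 0.01), Ccl2 at 1.05, and immediate early and stress genes 0 of 17 (median -0.20). Wnt targets had 2 higher and 1 lower of 13 (median -0.23), with Notum at 1.77 and Lef1 at -1.07. Housekeeping genes had a median of -0.10, with 1 of 17 at least 2-fold higher. The small medians of endothelial, megakaryocyte, inflammatory, immediate early and housekeeping genes also changed sign under at least 1 other processing.

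Over all genes, 924 of the 17639 measured (5.24%) were at least 2-fold higher in the SiO2-3TF-3C spleen than in the SiO2 spleen and 245 (1.39%) at least 2-fold lower. The lower genes numbered 40 with normexp background correction and 555 with no filter on dim genes. Of the higher genes 218 rest on a bound, since they were not well above background in the SiO2 spleen. The highest bounds included Fgg, Rbp4 (at least 1465-fold), Ttr, Serpina3k and Cyp2c68. Among genes well above background on both arrays the largest log2 differences, after Ahsg and Alb, included Kng1, Ces3a, Fgb, Mup20, Ambp at 9.53, Apoh at 9.41, Mup3, Bhmt, Apoc3 at 9.25 and Cyp2f2. The lowest included the odorant receptor Olfr1500 (8.01-fold lower), the protease gene Cts7, Tcl1b4 at -2.70, Fmr1nb at -2.65, Srp54b at -2.62 and Timm8a2 at -2.24. Fmr1nb was at 0.08 in the authors' deposited values. The lower bounds included Ntsr2 (at least 4.70-fold lower), Csdc2 and Casq1. With genes at least 2-fold higher in liver left out, a choice made after the data were seen, 184 genes remained at least 2-fold higher.

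The second comparison set normal liver against the SiO2 spleen and gives the scale on which the first can be read. Hepatocyte genes were higher in liver for 209 of 213 members, with a median log2 difference of 7.57. Alb differed by 10.18 ± 0.22, Hnf4a by 11.56 ± 0.35, Cyp2e1 by 9.93 ± 0.24 and Ces1d by 10.93, while Ttr was at least 4452-fold higher and Apoa1 at least 2812-fold. The plasma protein, coagulation, complement, acute phase and cytochrome P450 lists had medians of 9.46, 9.57, 7.32, 6.28 and 8.55. Phase 2 and transporter, bile acid, urea cycle, glucose, amino acid and fatty acid genes had medians of 7.10, 7.12, 5.42, 6.18, 8.02 and 4.21. The transcription factor list had a median of 3.31, with Foxa3 at least 87.0-fold higher and Gata4 at 0.78. Central and portal vein hepatocyte lists had medians of 4.83 and 8.23, female- and male-predominant lists 7.51 and 5.45, and the hepatoblast and biliary list 0.80. Of the Kupffer list 4 of 9 genes were higher, with Clec4f at 9.26 and Vsig4 at 7.01, and of the stellate cell list 9 of 13, with Colec11 at 6.21.

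Most lists of spleen and blood cell genes were lower in liver than in the SiO2 spleen, with medians from -1.46 for B cells to -0.70 for macrophages and dendritic cells. Of 46 lymphocyte genes 37 were at least 2-fold lower, 0 were higher and 9 were in between, with a median of -1.41 (2.66-fold). The medians were -1.46 for B cells, -1.40 for T and NK cells, -1.32 for megakaryocytes and platelets, -1.31 for neutrophils and mast cells, -1.24 for spleen stroma and -1.24 for the cell cycle. All 46 lymphocyte genes were well above background on the liver array, and so were the spleen organ regulators Tlx1 at -1.66 ± 0.21, Nkx2-5 at -1.22 ± 0.20 and Nkx2-3 at -1.25 ± 0.20. The follicle chemokine Cxcl13 was at -1.44. Erythroid genes had a median of -0.75, with 12 of 26 at least 2-fold lower, among them Epb42 at -1.52. Plasma cell genes had a median of -1.18, macrophage and dendritic cell genes -0.70 and inflammatory genes -0.90. Extracellular matrix and fibroblast genes had a median of -0.85, with 30 of 70 at least 2-fold lower and 4 higher. Of 6693 genes above the 75th percentile of the SiO2 spleen array, 1421 were at least 2-fold lower in liver, and 45 (0.672%) at least 4-fold lower. In the other direction, 974 (14.3%) of 6816 genes above the 75th percentile of the liver array were at least 4-fold lower in the SiO2 spleen. Interferon response, endothelial, mesothelial and Wnt target genes had medians of 0.51, 0.35, 1.38 and 0.52, skeletal muscle and immediate early genes -0.51 and -0.49, and housekeeping, pancreatic acinar, pancreatic islet and adipocyte genes 0.04, 0.13, 0.31 and -0.18. Those of plasma cell, skeletal muscle, Wnt target, housekeeping, acinar and adipocyte genes changed sign under at least 1 other processing.

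In all, 2670 of 17358 genes were at least 2-fold higher in liver than in the SiO2 spleen and 2946 at least 2-fold lower. The largest differences measured on both arrays included Mug1 at 11.65, Ces3a at 11.64, Hnf4a, Ambp at 11.43, Rgn at 11.40, Kng1, Fgb, Plg at 11.30, Cfi, Mup3, Pck1 and Ces1d. The lowest included Olfr1500 at -4.91, the nuclear lamin gene Lmnb1 at -4.24, Fmr1nb at -3.97, Srp54b at -3.88, Efna2 at -3.82, Myo5c at -3.18, Zc3h12d at -3.12 and the B cell kinase Btk at -3.01. Fmr1nb was at 0.59 in the authors' deposited values. Only 139 genes were at least 4-fold lower in liver, against 1359 at least 4-fold higher.

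The third comparison asks how far the SiO2-3TF-3C spleen stood from normal liver. Hepatocyte genes were lower in the SiO2-3TF-3C spleen than in liver for nearly every member. Of 213 measured 202 were at least 2-fold lower, 0 were higher and 11 differed by less than 2-fold, with a median log2 difference of -2.91 (7.51-fold). Hnf4a was at -3.19 ± 0.20, Cyp2e1 at -3.03, Otc at -3.46, Apoa1 at -3.48 and Krt18 at -3.51. The medians of the hepatocyte lists lay close together, at -2.31 for plasma proteins, -2.73 for coagulation, -2.40 for complement, -2.90 for acute phase, -3.03 for cytochrome P450, -2.99 for phase 2 and transporters, -2.83 for bile acids, -2.69 for the urea cycle, -2.87 for glucose, -3.14 for amino acids, -2.93 for fatty acids and -2.83 for transcription factors. The Kupffer cell genes Clec4f and Vsig4 were at -2.85 and -2.90, and the stellate cell gene Colec11 at -3.42, while the medians of the Kupffer cell, stellate cell and hepatoblast and biliary lists were nearer to 0, at -1.16, -1.30 and -0.58. The 479 genes at least 32-fold higher in liver than in the SiO2 spleen had a median of -3.26, which is 9.61-fold lower in the SiO2-3TF-3C spleen. The 80 brightest of them on the liver array had a median of -2.37 and the other 399 a median of -3.37 with a standard deviation of 0.51 over genes. Alb at -0.19, Mup20 at -0.48 and Fabp1 at -0.62 were among those nearest to the liver level.

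**Figure D2:**
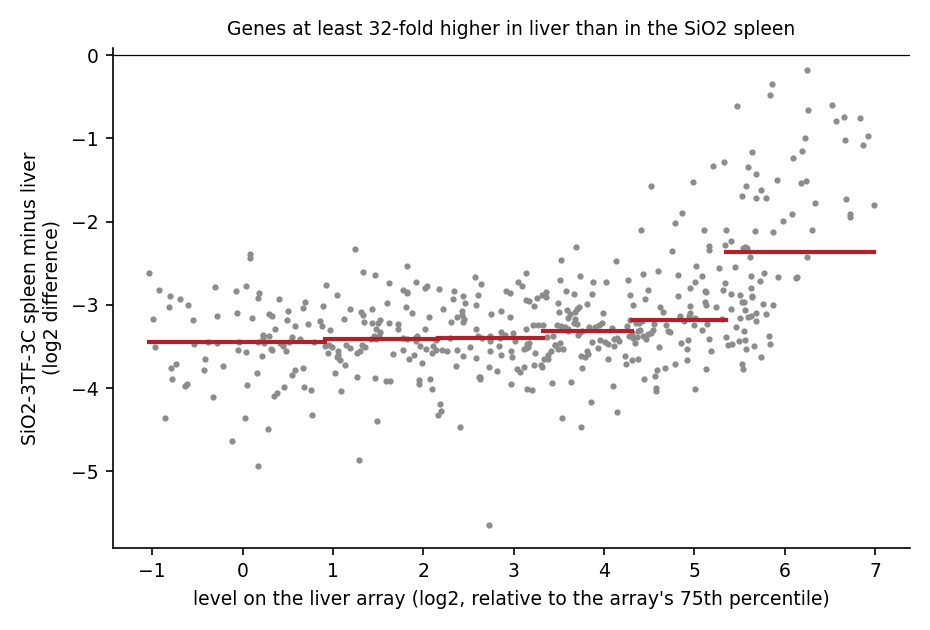
Log2 difference between the SiO2-3TF-3C spleen and the liver array (y axis) against the level on the liver array (x axis, log2 relative to the 75th percentile) for the 479 genes at least 32-fold higher in liver than in the SiO2 spleen. Red bars are medians of 6 bins of liver level, which go from -3.45 in the dimmest to -2.37 in the brightest.

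Lists of blood-forming and spleen genes had higher medians in the SiO2-3TF-3C spleen than in liver, though many members did not pass 2-fold. Spleen stroma genes had a median of 0.96, with 7 of 14 at least 2-fold higher and 1 lower. Of 26 erythroid genes 17 were at least 2-fold higher (median 2.44), with Epb42 at 3.92, Rhd at 3.84 and Kel at 3.72. The largest differences of the comparison outside that list included Btnl10 at 4.65, the membrane skeleton gene Add2 at 3.97, Trim10 at 3.88, Cldn13 at 3.82 and Rsph1 at 3.82. Rhag was at least 6.56-fold higher. Cell cycle genes were higher for 24 of 29 (median 1.83), with Mki67 at 2.88, and neutrophil and mast cell genes for 16 of 22 (median 1.69), with Prg2 at 3.47. Megakaryocyte and platelet genes were higher for 11 of 13 (median 1.29) and plasma cell genes for 6 of 9 (median 1.53). Lymphocyte genes had a median of 0.90, with 14 of 46 at least 2-fold higher, and extracellular matrix and fibroblast genes one of 0.69, with 15 of 70 higher and 4 lower. Over all genes, 1848 of 17212 were at least 2-fold higher in the SiO2-3TF-3C spleen than in liver and 2729 at least 2-fold lower. These numbers were 861 and 1867 with normexp background correction, and 1708 and 1702 in the authors' deposited values, so the balance of the directions depends on the processing. The lowest measured on both arrays was the pseudogene Serpina4-ps1 at -5.65, followed by genes that included Hao2 at -4.94, Inhbe at -4.86, Egfr at -4.47, Hsd3b5 at -4.47, Vnn1 at -4.40, G6pc at -4.37 ± 0.20, Foxq1 at -4.36 and Lbp at -4.33. Serpina7, which encodes a thyroxine carrier, was at least 28.3-fold lower.

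Across 17903 genes well above background on at least 1 array, the log2 levels of the SiO2-3TF-3C spleen correlated with those of the SiO2 spleen at r = 0.941 and with those of liver at r = 0.932, while liver and SiO2 spleen correlated at r = 0.829. These are correlations across genes, which are not independent replicates. RNA of the SiO2 spleen kind in the liver sample, a candidate taken up in the last part, may raise the correlations with liver. Of 894 genes at least 2-fold higher in the SiO2-3TF-3C spleen among the 17124 measured in both comparisons, 740 (82.8%) were also at least 2-fold higher in liver, where 132 would be in common for independent lists. Among 245 genes at least 2-fold lower, 130 were also lower in liver, against 42.1 for independent lists. That number was 28 with normexp background correction and 254 with no filter on dim genes. The erythroid genes Epb42 and Kel (at -1.52 and -1.38 in liver) were among 57 genes that were higher in the SiO2-3TF-3C spleen and lower in liver. Both comparisons use the same SiO2 spleen array. Simulated arrays with no difference shared a median of 23 higher and 24 lower genes through it. Over 16085 genes measured on all 3 arrays the log2 differences had a covariance of 0.964 against 0.0249 in the simulation, and a correlation of 0.776 against 0.495. The control array cannot be split, so part of the excess may come from it.

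**Figure D3:**
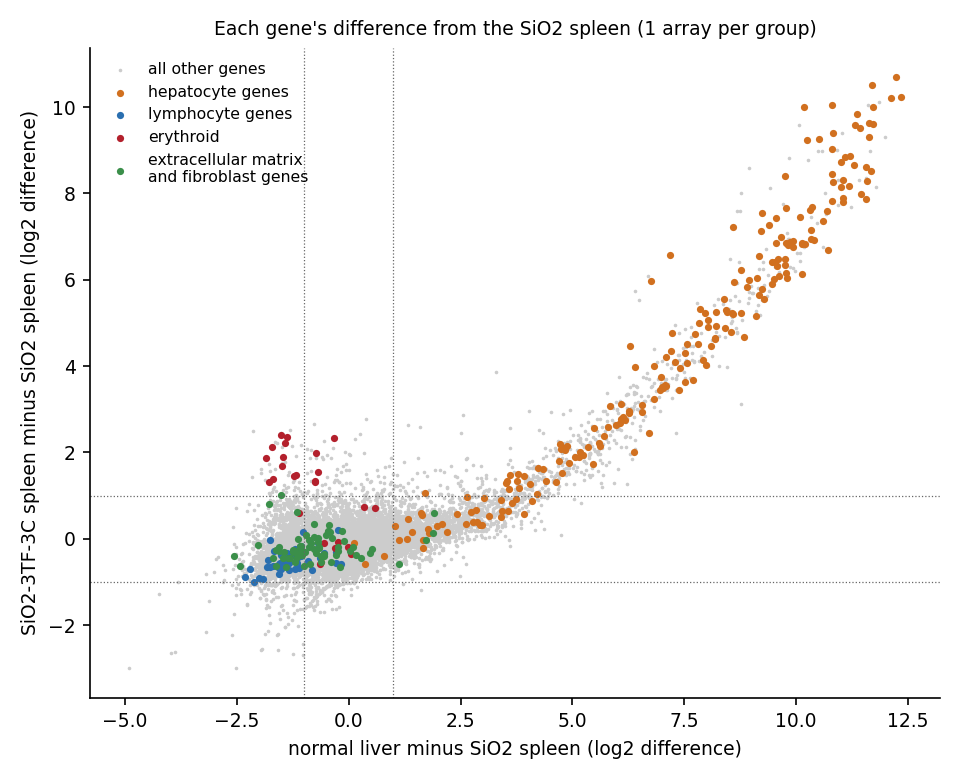
Log2 difference of each gene from the SiO2 spleen array, in normal liver (x axis) and in the SiO2-3TF-3C spleen (y axis), with 1 array per group and dotted lines at 2-fold. Most hepatocyte genes follow a band (median 7.57 on the x axis and 4.49 on the y axis), with some, such as Alb, above it. Of 26 erythroid genes 16 lie above the upper 2-fold line of the y axis.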

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

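Among the control spots, which no comparison above uses, 1 of the 10 E1A control probes stood out. Its median over 32 spots was an intensity of 194.6 on the SiO2 spleen array, against 29.3 on the SiO2-3TF-3C spleen array and 12.4 on the liver array, with median negative control spots at 1.94, 1.56 and 1.85.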

How the results depend on the processing

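Under the other processings, of which 2 were added after the data were seen, 40 of 195 values of the main results moved. A move is a change of over 1.5 times for counts and of over 0.05 for correlations. For medians it is a change of over the spread of replicate spots, 0.0921 to 0.106. No main median changed sign. Scaling to the median or to housekeeping genes moved no count or median of the main results past these limits, and cannot change correlations. No spot was saturated, so leaving out saturated probes tested nothing. The cause of the changes below was not tested, except that a 4-fold rule, a stricter filter and leaving out genes change counts by construction. The deposited table has fewer probes and also other values, so the effect of its size cannot be told apart from that of its processing. Genes at least 2-fold higher in the SiO2-3TF-3C than in the SiO2 spleen (924) numbered 592 with normexp, 489 at 4-fold and 184 without genes higher in liver. Those lower (245) numbered 40 with normexp, 156 in the authors' deposited values, 161 among genes measured on all arrays, 555 with no filter on dim genes and 19 at 4-fold. For liver against the SiO2 spleen, genes higher (2670) numbered 1774 in the deposited values and 1359 at 4-fold, and genes lower (2946) 1633 with normexp and 139 at 4-fold. For the SiO2-3TF-3C spleen against liver, genes higher (1848) numbered 861 with normexp and 221 at 4-fold, and genes lower (2729) 1702 in the deposited values and 1136 at 4-fold. Genes higher in both against the SiO2 spleen (740) numbered 461 at 4-fold, and genes lower in both (130) 28 with normexp, 254 with no filter and 6 at 4-fold.

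The median log2 difference of hepatocyte genes between the spleen samples (4.49) was 2.80 with normexp, 4.67 in the deposited values, 4.31 with the mean over probes, 3.17 among genes measured on all arrays and 4.63 with no filter. Between liver and SiO2 spleen (7.57) it was 5.83, 7.69, 6.48 and 7.74 with normexp, the deposited values, genes measured on all arrays and no filter, and 7.40 with quantile normalization. Between SiO2-3TF-3C spleen and liver (-2.91) it was -2.65 with normexp, -2.73 with quantile normalization and -2.68 in the deposited values. For lymphocyte genes in the last comparison (0.90) it was 1.09 with quantile normalization and 1.06 in the deposited values. Matrix and fibroblast genes (-0.27, -0.85 and 0.69 in the 3 comparisons) were at -0.18, -0.53 and 0.34 with normexp, and at 0.83 in the last with the deposited values. The correlation of liver and SiO2 spleen (0.829) was 0.885 with no filter. Among the other list medians, run after the data were seen, 333 of 1107 values moved by over the spread of replicate spots. They included 95 of 123 with normexp and 88 of 123 in the deposited values. A further 1 changed sign from a median past 2-fold. That was the median of plasma cell genes in liver against the SiO2 spleen (-1.18), at 0.0201 in the deposited values. These numbers leave out the sex genes, of which only Xist was measured and whose median for the same comparison (-1.01) reached 0.47 under another processing. Among 444 named differences of at least 2-fold, those of Fmr1nb changed sign in the deposited values, to 0.0759 and 0.59. No paired analysis was possible because each group has 1 array.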

Other observations

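The tests in this part were chosen after the results they bear on were seen. The SiO2-3TF-3C spleen array was set against the best mix of the other arrays. That mix took 0.774 of the SiO2 spleen and 0.103 of the liver array. It left a standard deviation of 0.38 on the log2 scale over 16085 genes, against 0.81 for the SiO2 spleen alone. It came within 2-fold for 97.6% of genes, with 314 at least 2-fold above it and 76 below. Most of these genes already lay within 2-fold of the SiO2 spleen alone, against which 687 were at least 2-fold higher and 161 lower. By list, erythroid, cell cycle, neutrophil and mast cell, and plasma cell genes had median residuals of 1.64, 0.84, 0.80 and 0.54, and skeletal muscle genes of -0.47. B cell genes lay at -0.32 and spleen stroma genes at -0.05. Single genes outside the lists also lay far above the mix, and whether they share a function was not tested. Among them, chosen after their values were seen, were Rsrc2, Lca5l, Btnl10, Cldn13, Add2, Ankrd1 and Hpcal4 at 3.04, 2.91, 2.83, 2.81, 2.76, 2.59 and 2.48. Btnl10, Cldn13 and Add2 were lower in liver than in the SiO2 spleen (-2.15, -1.31 and -1.52). The erythroid genes Epb42 and Kel had the same pattern (-1.52 and -1.38). Rsrc2, Lca5l, Ankrd1 and Hpcal4 did not, at 3.29, 0.39, 0.26 and 0.15 in liver.

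Several liver genes fell short of the band that the others follow. Chosen after their values were seen, Egfr, Vnn1, Foxq1, G6pc, Lbp and Fgf21 lay at -1.39, -1.27, -1.28, -1.21, -1.18 and -1.19 against the mix, while the bright plasma protein genes Alb, Mup20 and Ahsg lay at 3.09, 2.80 and 2.53.

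B cell, T and NK cell, megakaryocyte and spleen stroma genes had similar medians in liver against the SiO2 spleen, spanning 0.23, whereas macrophage and dendritic cell genes (-0.70) and the whole erythroid list (-0.75) were nearer to 0 and spleen stroma genes had a standard deviation of 0.93. The tables argue against background signal, since the lymphocyte genes stood 6.09 above the lowest well-above-background level of that array, and against immune cells that live in the liver as the whole source, since the spleen organ regulators Tlx1, Nkx2-5 and Nkx2-3 had a median of -1.25, close to the lymphocyte median of -1.41. RNA of the SiO2 spleen kind in the liver sample is a candidate explanation that the span of 0.23 allows, for 4 lists picked after the data were seen. Such RNA would keep spleen genes from falling far below the lymphocyte median. Of 6693 genes above the 75th percentile of the SiO2 spleen array only 45 were at least 4-fold lower in liver. Over all genes 139 were, among them the B cell kinase Btk and Lmnb1, which a constant share of such RNA does not account for. Each of these genes is represented by 1 probe, however. In this comparison, probes of the same gene differed by over 1 log2 in 19.6% of genes with several measured probes. The 16 erythroid genes at least 2-fold higher in the SiO2-3TF-3C spleen had a median of -1.40 in liver against the SiO2 spleen. They were selected by a difference from the same SiO2 spleen array, so they do not settle whether such RNA was present. At which step such RNA would have entered was not tested. If it did enter, differences of spleen genes between liver and either spleen sample understate the true ones. The correlations with liver and the liver weight of the mix would be affected as well.

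Most liver genes in the SiO2-3TF-3C spleen lay near a common fraction of the liver level. Compression of the brightest signals may account for genes that came close to the liver level, such as Alb. The brightest 80 lay 0.995 above the rest, but they include those same genes, so this is not a separate test of compression. Other bright genes such as Hamp, at -3.63, did not come close. Liver tissue or liver RNA in the spleen sample is a candidate explanation for the common ratio. The 10 genes of Kupffer, stellate and endothelial cells at least 4-fold higher in liver had a median residual of -0.14 from the mix. That value cannot decide it, because only genes well above background on all 3 arrays could enter. For genes little past 4-fold, the mix also lies close to the SiO2 spleen level. Hepatocyte-like cells made from spleen cells cannot be told apart from liver material, because a complete hepatocyte profile gives the same ratio. Transcription factors differed from the other hepatocyte genes by -0.50, within the limit of 1 set for the test. The genes Clec4f, Vsig4 and Colec11 are a part that hepatocyte-like cells alone would not bring, and cells of those kinds that formed in the spleen stay possible and untested.

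Of 26 erythroid genes, 16 were at least 2-fold higher in the SiO2-3TF-3C spleen than in the SiO2 spleen and 17 than in liver. The tables argue against liver material as the cause, since the erythroid list was higher than on both other arrays. Its medians were 1.36 against the SiO2 spleen and 2.44 against liver. Its residual of 1.64 from the mix of the other arrays follows from those differences and is not separate evidence. Red blood cells left in the spleen stay open, because the globin genes, at a median difference of -0.19, lie at 5.91 on the SiO2 spleen array, among the brightest signals, which may be compressed, and because it is not known whether the blood protocol's globin removal was applied to these tissues. Dividing red cell precursors in the treated spleen are a hypothesis that these values cannot decide. Cell cycle genes lay 0.84 above the mix, but they were already higher than on both other arrays (medians 0.56 and 1.83). That list also does not single out red cells. With 1 pool per group, a difference between pools that has nothing to do with the treatment was not tested.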
